A study of Mus musculus with 9 samples.

How the data were processed

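Total RNA was taken from the shaved back skin of BALB/c mice, wild type, aged 6 to 8 weeks and kept free of specific pathogens, in 3 groups of 3 libraries: vaseline for 7 days, imiquimod (IMQ) for 7 days, and IMQ for 7 days with a bergapten gel for 2 days. Libraries were made from 1.3 µg of total RNA extracted with RNAiso Plus, per the labels' protocols. Reads were trimmed with Trimmomatic, aligned to GRCm39 with HISAT2 and counted per gene with HTSeq 0.6.0, per the submitters' processing notes. The deposited table holds raw read counts, 1 column per library, and beside them FPKM values made by the authors. The counts are whole numbers without scaling between libraries, so differences in depth and composition had to be normalised here. The FPKM columns were used only to check the counts: 0 genes had a count above 0 with an FPKM of 0. The deposited quality sheet gives raw reads, bases in Gb, a mean quality score per library, and GC, Q20 and Q30 as percent.

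The table has 56861 rows, of which 55416 are Ensembl genes, 1443 are loci assembled by the authors and 2 name no gene. Symbols found on more than 1 row (108) were kept apart by gene ID. The reference annotation in hand (release M21, GRCm38) shared 52083 of the IDs, but only 1498 had the same start, so coordinates were taken from the deposited table, on GRCm39. Counting only unique alignments to genes would leave families of similar sequence, such as Sprr2, Lce3, Serpinb3, Stfa, Mrgprb, Trgc and the immunoglobulins, with uncertain counts, and no source states how such reads were treated.

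Raw reads per library ran from 42017796 to 53491700 and counted reads from 15855439 to 19862905 (vaseline 16080479 to 18757911, IMQ 18890579 to 19456060, IMQ with bergapten 15855439 to 19862905), or 37.13 to 38.38 counts per 100 raw reads. GC was 50.57% to 51.185% and Q30 93.92% to 95.515%. Between 24136 and 25148 genes had a count. The 20 genes with most counts took 16.48% to 17.08% of counts in vaseline, 8.44% to 9.42% in IMQ and 10.37% to 11.05% with bergapten. Normalization factors lay between 0.9524 and 1.0572. No pair of replicates in a group had identical values, and their counts differed by 10.85 to 80.01 times the variance that counting alone gives.

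All 9 libraries were fitted in 1 group-means model with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, TMM normalization). Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 18005 genes, 557 of them assembled loci, with a common biological coefficient of variation of 0.187. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, and genes with an adjusted p under 0.05 are described as rising, falling or changed. Standard errors of the log2 fold change were computed as its absolute value over the square root of the F statistic. A prior count of 2 was used only for log2 CPM values. Values with ± are means and SDs over the 3 libraries of a group. A fold against a group without counts was set against a floor of 3 counts over the group.

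A set of 31 gene lists was fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives except 1. The lists were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01 between genes, adjusted over the lists. Each was tested again with the correlation estimated from the list itself, and with fry. Genes were named by this rule: in each of the first 2 comparisons the 8 largest rises and 8 largest falls among changed genes whose groups did not overlap, with a mean of at least 1 CPM and a symbol that is not a predicted name, and 4 and 4 in the third. Up to 4 members with the smallest raw p were taken from each list, and Il17a, Il17f, Il22, Il23a, S100a8, S100a9, Krt16, Cyp1a1 and Cyp1b1 always. Not every gene that the rule takes is printed. Some list members that the table carries under no matching name were not analysed here.

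The procedure was tested on simulated counts with a seeded set of changed genes. Each gene had 1 mean taken over all libraries and the same spread in every group, with the real library sizes. Genes were drawn independently of each other. In the real data the mean variance of log2 CPM was 0.238 in IMQ skin against 0.1002 in vaseline, and list members were correlated. The rates below may therefore not carry over to the real data. For IMQ against vaseline (17655 genes) it recovered 20.9%, 53.7% and 86.4% of genes changed 1.5-fold, 2-fold and 4-fold, and 8.5% of its calls were false. For bergapten against IMQ (17667 genes) the shares were 9%, 55.2% and 83.3%, with 10.1% of calls false, and for bergapten against vaseline (17674 genes) 14.9%, 62.7% and 86.4%, with 6% false. The false share lay above the nominal 5% in each. For lists, 5 of 5 lists shifted by 0.5 log2 units were called in bergapten against IMQ (17626 genes), as was 1 list that had not been shifted.

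The alternatives were RLE size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter of at least 1 CPM in 3 libraries, a fit of only the 6 libraries compared, replicate number as a block, a minimum fold of 2, and leaving out each library in turn. After the data were seen, 1 alternative was added that leaves out replicate 2 of IMQ and of IMQ with bergapten together. Pathway names carried by the deposited table were tested with Fisher's exact test on 1998 annotated genes, adjusted over 206 pathways, separately for genes that rose and fell.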

Results

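RNA sequencing measured gene expression in the shaved back skin of BALB/c mice aged 6 to 8 weeks. There were 3 groups of 3 libraries: skin given vaseline for 7 days, skin given imiquimod (IMQ) for 7 days, and IMQ-challenged skin that also received a bergapten gel for 2 days. IMQ is an agonist of Toll-like receptor 7 that is applied as a cream to give mice a psoriasis-like skin inflammation, and bergapten is a plant furanocoumarin. The labels describe no IMQ group with an empty gel and give neither the hour of collection nor the time since the last IMQ dose. The libraries held 42017796 to 53491700 raw reads, of which 15855439 to 19862905 per library were counted to genes. Of the genes in the table, 18005 had enough counts to be tested. The labels do not say that the replicates were separate animals, so p-values measure the spread between these samples, which may be technical. That spread was estimated per gene from all 3 groups together.

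The first principal component of log2 CPM (counts scaled to a common library size) held 64.3% of the variance and separated the 3 vaseline libraries, at -96.8 to -90.8, from the 6 IMQ-challenged ones, at 33 to 56.7. The second component held 13.2% and was set mainly by IMQ replicate 2, at 71.1. The mean variance within a group was 0.238 in IMQ skin on the log2 CPM scale, against 0.1002 in vaseline and 0.1021 with bergapten. In bergapten replicate 2, the 18S ribosomal RNA gene Rn18s, chosen after the values were seen, took 1.794% of all counts, against 0.179% to 0.27% in the other 8 libraries.

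**Figure D1:**
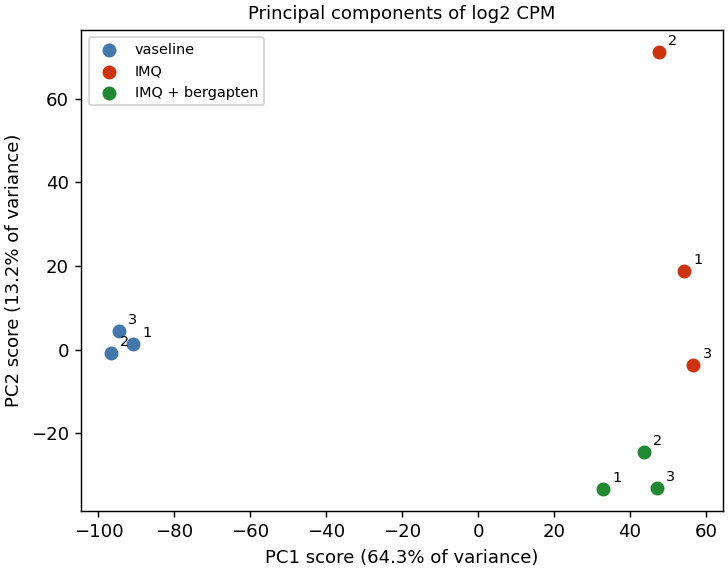
Principal components of log2 CPM over the genes tested, 1 point per library with its replicate number, with the share of variance on each axis. The vaseline libraries lie at -96.8 to -90.8 on the first component and IMQ replicate 2 lies at 71.1 on the second.

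The first comparison, IMQ against vaseline, asks what the challenge did to the skin. Of the gene lists tested, those of keratinocyte stress, of neutrophils and of the keratinocyte response to interleukin (IL)-17 had the 3 highest medians. S100a8, which encodes an antimicrobial calcium-binding protein of neutrophils and stressed keratinocytes (ENSMUSG00000056054, GRCm39 chromosome 3, 90576285 to 90577342, plus strand), went from 1.26 ± 0.476 to 2380 ± 930 CPM (SD, n = 3 per group). Krt16, a keratin of hyperproliferative epidermis (ENSMUSG00000053797, chromosome 11, 100136917 to 100139728, minus strand), went from 5.34 ± 1.86 to 2196 ± 1019 CPM. Collagens, skeletal muscle genes and sebaceous gland genes fell: Col1a2, a chain of type I collagen, went from 33080 ± 388 to 3741 ± 1637 CPM, and Casq1, the calcium store protein of fast muscle, from 292 ± 14.5 to 9.55 ± 3.26 CPM. In the edgeR quasi-likelihood test, 7783 genes passed an adjusted p of 0.05, of which 4143 rose and 3640 fell, and 3299 of the 7783 changed at least 2-fold. The 2 groups did not overlap for 52.3% of all genes tested, where chance gives 10%.

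All 28 measured genes of the hyperproliferation keratins and stress barrier list rose, with a median log2 fold change of 8.62, or 8.53 with the 4 members that had no count in vaseline set at their lower bound. Among them were Stfa3, a cysteine protease inhibitor (8.80, SE 0.35, adjusted p = 7.05e-07), Serpinb3a, a serine protease inhibitor (11.30, SE 0.64, adjusted p = 6.57e-06), and Sprr2b, a cornified envelope precursor that had no count in vaseline and was at least 6475-fold higher in IMQ skin, taking 3 counts over the group as the floor. The list passed the camera test (adjusted p = 4.97e-21; adjusted p = 0.212 with an estimated correlation). The Sprr2, Lce3, Serpinb3 and Stfa genes are families of similar copies that may share reads, so the split between their members is uncertain. Of 26 genes in the IL-17 and IL-36 keratinocyte response, 23 rose, among them the IL-36 cytokines Il1f6 (7.20, SE 0.26, adjusted p = 2.44e-07) and Il1f9 (3.86, SE 0.14, adjusted p = 2.44e-07). That list had a median of 3.99 (camera adjusted p = 4.66e-13; adjusted p = 0.17 with an estimated correlation). Of 19 genes of the IL-23 and IL-17 cytokine axis, 13 rose over all genes tested and 15 adjusted over the list alone (camera adjusted p = 3.92e-05; adjusted p = 0.212 with an estimated correlation). Il23a, the specific subunit of IL-23, rose by 3.41 (SE 0.59, adjusted p = 0.0012). Il17a, a cytokine of the same axis (ENSMUSG00000025929, chromosome 1, 20801129 to 20804720, plus strand), went from 0.115 ± 0.0906 to 8.69 ± 8.67 CPM (adjusted p = 0.00392), and its relatives Il17f and Il22 had few counts in vaseline, with means of 9.56 and 1.63 CPM in IMQ skin.

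Immune cell lists moved in different directions. Of 22 neutrophil genes 19 rose and 1 fell, including the lectin receptor Clec4d (4.87, SE 0.31, adjusted p = 2.7e-06) and the chemokine receptor Cxcr2 (5.08, SE 0.47, adjusted p = 6.82e-05). The neutrophil list had a median of 4.72, or 4.44 with the member at 0 counts at its bound (camera adjusted p = 3.46e-08; adjusted p = 0.285 with an estimated correlation). Monocyte and macrophage genes (14 rose and 1 fell of 24, led by the Fc receptor Fcgr4 at 4.37), T cell genes (12 rose and 2 fell of 23, including Icos at 2.45) and gamma-delta T cell genes (8 rose and 1 fell of 11, including Trdc at 2.17) passed with adjusted p of 0.000846, 0.00521 and 0.0244. With an estimated correlation these became adjusted p = 0.491, adjusted p = 0.212 and adjusted p = 0.475. B and plasma cell genes also passed (7 rose and 1 fell of 12, including Cd79b at 2.37; adjusted p = 0.0101, and adjusted p = 0.419 with an estimated correlation). Dendritic and Langerhans cell genes went the other way, with 12 of 22 lower and 3 higher. They included Cd74, the invariant chain of MHC class II (ENSMUSG00000024610, chromosome 18, 60936920 to 60945724, plus strand), which fell by 1.33 (SE 0.17, adjusted p = 0.000176), and Siglech, a marker of plasmacytoid dendritic cells, which fell by 2.62 (SE 0.26). The list passed with adjusted p = 0.0107, and adjusted p = 0.49 with an estimated correlation. Mast cell genes (7 rose and 1 fell of 14) and endothelial genes (8 rose and 1 fell of 18) did not pass as lists, with camera adjusted p of 0.0545 and 0.0812. The mast cell list passed without vaseline replicate 3 (adjusted p = 0.0132), IMQ replicate 1 (0.0306) or IMQ replicate 3 (0.0442), and with replicate number as a block (0.0448). The endothelial list passed without vaseline replicate 2 (0.0475) or IMQ replicate 3 (0.0169).

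Of the cell cycle genes, 24 of 32 rose and 1 fell, with Rrm2, a subunit of ribonucleotide reductase, up by 1.85 (SE 0.31). The cell cycle list passed with adjusted p = 3.98e-05 (adjusted p = 0.521 with an estimated correlation), and its median in single IMQ libraries was 0.21 in replicate 2 against 1.49 and 1.63 in the others. Homeostatic differentiation genes were mixed, with 15 of 30 higher and 3 lower: the desmosomal cadherin Dsc1 rose by 2.43 (SE 0.10) while the keratin gene Krt77 fell by 7.43 (SE 1.10). That list passed with adjusted p = 0.00214 (adjusted p = 0.521 with an estimated correlation). Basal epidermal genes split 8 to 3 of 14, with Cdh3, a cadherin, up by 1.98, and as a list they did not pass (adjusted p = 0.0681, but 0.0497 without vaseline replicate 3 and 0.0491 without IMQ replicate 3). Of 30 cytosolic ribosomal protein genes 28 rose, by a median of 0.62 (adjusted p = 6.29e-11; adjusted p = 0.419 with an estimated correlation).

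All but 1 of 22 skeletal muscle genes fell, with a median of -1.63 (adjusted p = 1.27e-12; adjusted p = 0.17 with an estimated correlation). Fibroblast and collagen matrix genes fell in 18 of 24 cases and rose in 3. Sparc, a collagen-binding matrix protein, fell by 3.19 (SE 0.28, adjusted p = 4.25e-05), and the list passed with adjusted p = 4.05e-06 (adjusted p = 0.419 with an estimated correlation). Sebaceous gland genes fell in 16 of 25 cases, with the desaturase Scd3 down from 614 ± 43.1 to 19.5 ± 11.2 CPM, and 1 rose (list adjusted p = 3.1e-05; adjusted p = 0.419 with an estimated correlation). Adipocyte genes (7 fell of 19), nerve and Schwann cell genes (9 fell of 13) and mitochondrial genome genes (4 fell of 11) passed with adjusted p of 0.00481, 0.000271 and 0.0109. With an estimated correlation these became adjusted p = 0.521, adjusted p = 0.419 and adjusted p = 0.475. The adipocyte median was -2.24 in IMQ replicate 2 against -0.23 and -1.08 in the others. Hair follicle growth-phase genes rose in 6 of 18 cases. That list did not pass (adjusted p = 0.0722), but did without any 1 of the vaseline libraries (0.036, 0.0411 and 0.0334), IMQ replicate 1 (0.00241) or IMQ replicate 2 (0.0238). It also passed with replicate number as a block (0.0457). Krt71, chosen after the values were seen and a keratin of the follicle's inner root sheath, stood at 252.8 CPM in IMQ replicate 3 against 0.468 and 0.863 CPM in the other IMQ libraries. Among the largest falls were the secreted inhibitor gene Serpina3b (-7.86, SE 0.32, adjusted p = 7.05e-07) and Mrgprb11-ps, a pseudogene of the Mrgprb receptor family that may share reads with its relatives and was at least 489.5-fold lower, with no count in IMQ skin.

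Clock genes changed in both directions: 9 of 16 fell, including Dbp (-3.44, SE 0.22, adjusted p = 4.67e-06) and Nr1d1 (-2.61, SE 0.15), and 4 rose, including Cry1 (1.70, adjusted p = 1.5e-05). The circadian list passed with adjusted p = 0.0342 (adjusted p = 0.497 with an estimated correlation). NF-kappaB targets rose in 9 of 22 cases and fell in 1, including the adhesion molecule Vcam1 (3.57, SE 0.27, adjusted p = 1.61e-05), and the list passed with adjusted p = 0.0422 (adjusted p = 0.521 with an estimated correlation). Without vaseline replicate 1, IMQ replicate 1 or IMQ replicate 3 both lists lost their call, at adjusted p of 0.0653, 0.0551 and 0.0824 for the clock and 0.092, 0.0609 and 0.0872 for NF-kappaB. The type I interferon list did not pass (of 28, Rsad2 rose, a call lost without any 1 vaseline library at adjusted p up to 0.0812, and Usp18 fell; list adjusted p = 0.123), and its median per IMQ library was -0.29, -1.54 and 0.62. Without IMQ replicate 3 it passed downward (adjusted p = 0.000114). Aryl hydrocarbon receptor targets (6 rose and 2 fell of 15, adjusted p = 0.173), NRF2 antioxidant targets (9 rose and 2 fell of 22, adjusted p = 0.101, or 0.0468 without IMQ replicate 3), p53 targets (7 rose and 4 fell of 22, adjusted p = 0.451) and cholesterol synthesis genes (7 rose and 5 fell of 20, adjusted p = 0.327) did not pass as lists. Neither did itch and type 2 cytokine genes (5 rose and 6 fell of 19, adjusted p = 0.422) nor immediate early and heat shock genes (3 rose of 20, adjusted p = 0.822), whose median of -0.31 differed in sign from the test. Within these lists, Slc7a11, the cystine transporter, rose by 7.56 (SE 0.53) and Retnla, a product of alternatively activated macrophages, fell by 6.57 (SE 0.46). Cyp1a1, the classic aryl hydrocarbon receptor target, fell by 1.33 (SE 0.47, adjusted p = 0.0486), a call lost in 5 of 6 fits without 1 library (highest adjusted p = 0.11).

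**Figure D2:**
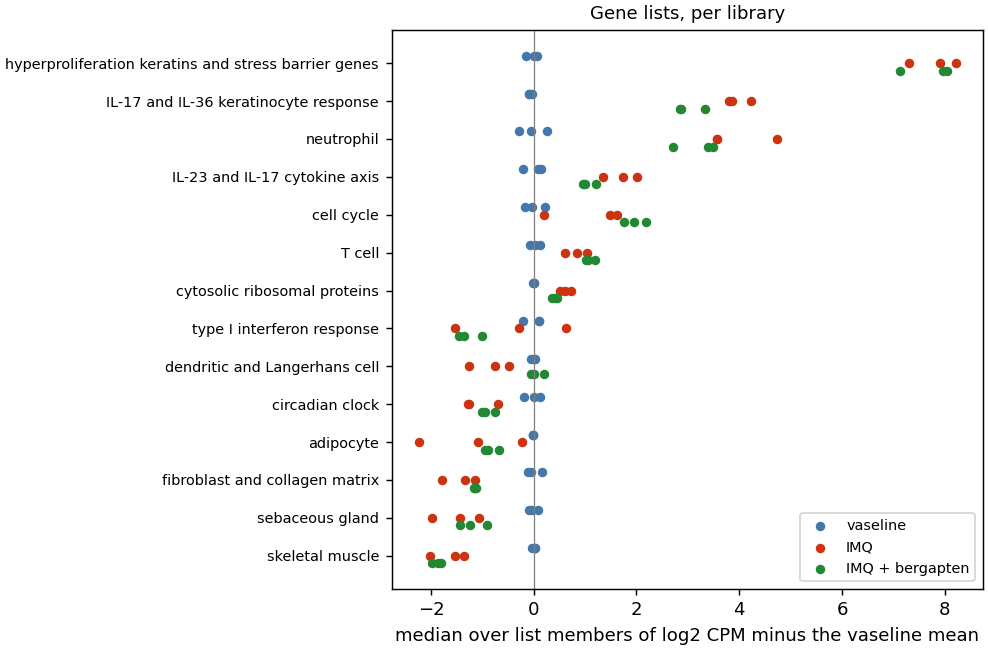
Median over the members of each of 14 gene lists of the log2 CPM minus the mean of the vaseline libraries, 1 point per library. The hyperproliferation list lies at 7.13 to 8.21 in all 6 IMQ-challenged libraries, and the dendritic and Langerhans cell list at -1.26 to -0.48 in IMQ skin and -0.05 to 0.21 with bergapten.

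The second comparison, IMQ with bergapten against IMQ alone, asks what changed in challenged skin that received the gel. Of 22 dendritic and Langerhans cell genes 8 rose and 1 fell: Cd74 went from 435 ± 102 to 944 ± 157 CPM (SD, n = 3 per group). The T helper cell marker Cd4 went from 6.18 ± 1.22 to 19.4 ± 2.42 CPM. Of 22 neutrophil genes 3 fell and none rose, with Clec4d at 24 ± 6.63 CPM in IMQ skin and 7.02 ± 1.89 CPM with bergapten. The adhesion molecule Vcam1 stood at 150 ± 52 and 38.4 ± 4.08 CPM. Muscle genes moved both ways: Casq1 rose 6.12-fold, while Trim63, a ubiquitin ligase that breaks down muscle protein (ENSMUSG00000028834, chromosome 4, 134042431 to 134056940, plus strand), fell from 237 ± 176 to 18.4 ± 5.83 CPM. The stress keratins did not change detectably, with Krt16 at 2196 ± 1019 and 1952 ± 386 CPM (adjusted p = 0.834). In the edgeR test 869 genes passed, of which 392 rose and 477 fell, and 355 of the 869 changed at least 2-fold.

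That count depended on single libraries and on which libraries were fitted. It was 1711 without IMQ replicate 3, and 139, 332 and 176 without bergapten replicates 1, 2 and 3. When only the 6 libraries compared were fitted, the count was 130. That fit leaves the vaseline libraries out of the estimate of the spread and has fewer libraries to make it from. The fit of all libraries assumes an equal spread in the groups, but the mean variance was 0.238 in IMQ skin and 0.1002 in vaseline. The naming rule looked at 144 genes, which include genes that had not passed and so had no call to lose. Of these 144, 45 lost a call in at least 1 fit without a library, so the share of calls lost was larger than 45 of 144. The groups did not overlap for any of the 869 genes, nor for 26.4% of all genes tested, where chance gives 10%.

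Adjusted over the list alone, 16 of the dendritic and Langerhans cell genes rose. Cd74 rose by 1.12 (SE 0.17, adjusted p = 0.00961) and the integrin gene Itgax by 0.73 (SE 0.11, adjusted p = 0.00768). The exception was Clec10a, a lectin of dermal dendritic cells and macrophages, which fell by 0.98 (SE 0.15, adjusted p = 0.0108). The list had a median of 0.96 (camera adjusted p = 1.11e-07; adjusted p = 0.675 with an estimated correlation) and was the only 1 of 31 lists to pass the fry test for movement in 1 direction (adjusted p = 0.0349). In this comparison 11 lists passed camera at the preset correlation. Of the 10 splits of the 6 libraries, 8 gave at least as many, the real one included. Cd4 rose by 1.64 (SE 0.23, adjusted p = 0.00657) as the only 1 of 23 T cell genes to change (list adjusted p = 0.434). Ighm, the constant region of immunoglobulin M, rose by 1.24 (SE 0.13, adjusted p = 0.00188) as the only 1 of 12 B and plasma cell genes (list adjusted p = 0.116, or 0.0374 without IMQ replicate 2 and 0.025 without bergapten replicate 3). Immunoglobulin genes may share reads.

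The neutrophil genes that fell were Clec4d, by 1.77 (SE 0.25, adjusted p = 0.00711), the decoy receptor Il1r2 by 1.26 (SE 0.17, adjusted p = 0.00686), and Retnlg by 3.64 (adjusted p = 0.0369, up to 0.127 without 1 library). Adjusted over the list alone, 8 fell. The neutrophil list had a median of -0.81 (adjusted p = 0.00258; adjusted p = 0.675 with an estimated correlation), and its call was lost without IMQ replicate 1 (adjusted p = 0.0612). In the IL-17 and IL-36 keratinocyte response 4 of 26 fell, and 7 adjusted over the list alone: Cxcl2 and Cxcl3, which attract neutrophils, the epithelial cytokine gene Il17c, and Tgm1, a transglutaminase of the cornified envelope. Without 1 library the call was lost in 2 of 6 fits for Cxcl3 (adjusted p up to 0.0594) and Tgm1 (0.0778) and in 4 for Il17c (0.164). Cxcl2 (ENSMUSG00000058427, chromosome 5, 91051730 to 91053797, plus strand) fell by 3.28 (SE 0.75, adjusted p = 0.0497), a call that no fit without 1 library kept (adjusted p = 0.0631 to 0.157). The list passed with adjusted p = 0.000654 (adjusted p = 0.675 with an estimated correlation). No gene of the IL-23 and IL-17 cytokine axis passed over all genes, and 5 of 19 fell adjusted over the list alone (list adjusted p = 0.0256; adjusted p = 0.675 with an estimated correlation). Without IMQ replicate 3 or bergapten replicate 1 that list did not pass (adjusted p of 0.186 and 0.0962). Il17a averaged 8.69 ± 8.67 CPM in IMQ skin and 0.983 ± 0.323 CPM with bergapten (log2 fold change -3.14, SE 0.90, adjusted p = 0.0883). Without 1 library the Il17a value ran from -3.68 to -2.04 and its adjusted p from 0.00234, without IMQ replicate 2, to 0.252, without bergapten replicate 3. Il23a had an adjusted p of 0.178. S100a8 stood at 1613 ± 664 CPM with bergapten (adjusted p = 0.456).

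All 32 cell cycle genes had higher estimates with bergapten, of which E2f1, Nusap1 and Foxm1 passed over all genes, calls lost in 2, 4 and 4 of 6 fits without 1 library (adjusted p up to 0.0767, 0.149 and 0.156). Against vaseline the list stood at 0.21 in IMQ replicate 2, at 1.49 and 1.63 in the other IMQ libraries and at 1.76 to 2.18 with bergapten, so the difference from IMQ was largest for replicate 2. The median log2 fold change was 0.73 (adjusted p = 3.07e-09; adjusted p = 0.675 with an estimated correlation). All 28 interferon genes had lower estimates, of which Usp18 and Rsad2 passed, each lost in 3 of 6 fits (adjusted p up to 0.0838 and 0.15), with a median of -1.11 (adjusted p = 8.78e-05; adjusted p = 0.801 with an estimated correlation). Against vaseline the interferon list stood at -0.29, -1.54 and 0.62 in IMQ replicates 1, 2 and 3 and at -1, -1.46 and -1.36 with bergapten, so the 2 groups overlapped, with IMQ replicate 2 lowest of all. Without IMQ replicate 3 that list did not pass (adjusted p = 0.186). Endothelial genes fell in 3 of 18 cases, including the receptor Flt1 (-0.70, SE 0.08, adjusted p = 0.00242) and Lyve1, a lymphatic marker (-1.49, SE 0.28, adjusted p = 0.0274, lost in 4 of 6 fits, up to 0.114). The endothelial list passed with adjusted p = 5.51e-05 (adjusted p = 0.675 with an estimated correlation). Fibroblast and collagen matrix genes passed upward (median 0.51, adjusted p = 0.00149; adjusted p = 0.675 with an estimated correlation). Of its 24 members Dpt, which encodes a collagen-binding protein, rose over all genes, 12 rose adjusted over the list alone, and the growth factor receptor Pdgfra and the cross-linking enzyme gene Lox fell. Those calls were lost in 5 of 6 fits for Dpt (adjusted p up to 0.127), 4 for Pdgfra (0.125) and 3 for Lox (0.14). Basal epidermal genes passed downward (Cdh3, Itga3 and Trp63 fell of 14, adjusted p = 0.0205; adjusted p = 0.675 with an estimated correlation), as did p53 targets with no member past the threshold of 22 (adjusted p = 0.0213; adjusted p = 0.675 with an estimated correlation). Without IMQ replicate 2 both missed the threshold (adjusted p of 0.0816 and 0.0502), and the basal list also without bergapten replicate 1 (adjusted p = 0.0555). Itga3 lost its call in 2 of 6 fits (up to 0.0655) and Trp63 in 4 (0.13). Cytosolic ribosomal protein genes had a median of -0.23, with Rps2 higher and Rps3 lower (lost in 4 of 6 fits, up to 0.135), and 17 of 30 fell adjusted over the list alone (adjusted p = 5.62e-07; adjusted p = 0.675 with an estimated correlation).

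Other lists did not pass but held single changed genes. Of 22 skeletal muscle genes (list adjusted p = 0.821) Casq1 and the mitochondrial creatine kinase gene Ckmt2 rose, by 2.61 (SE 0.24, adjusted p = 0.00188) and 1.31, and Myh4, a fast myosin heavy chain, Tnni2 and Atp2a1 fell, Myh4 by 1.73 (SE 0.21, adjusted p = 0.00492). Atp2a1 was outside the rule for naming genes and was added after the values were seen; its call was lost in 3 of 6 fits without 1 library (adjusted p up to 0.125). The muscle median of -0.06 and mean of 0.071 differed in sign. Among the largest rises and falls outside the lists, the water channel gene Aqp4 rose by 4.53 (SE 0.40, adjusted p = 0.00139) and the sarcomere-associated Ky went from 2.08 ± 1.44 to 33.7 ± 7.72 CPM (adjusted p = 0.00492). Trim63 fell by 3.68 (SE 0.55, adjusted p = 0.0151, up to 0.0721 without 1 library) and the secreted inhibitor gene Serpina3k fell by 4.91 (SE 0.70, adjusted p = 0.00714). Among clock genes Dbp, Per3 and Tef rose and Nfil3, a repressor of the same promoter elements, fell, with Dbp up by 1.74 (SE 0.21, adjusted p = 0.00492; list adjusted p = 0.795). Of the aryl hydrocarbon receptor targets Ahrr rose, a call lost in 5 of 6 fits without 1 library (adjusted p up to 0.161), and Cyp1b1 fell from 128 ± 54.6 to 34.7 ± 5.94 CPM (adjusted p = 0.0126, up to 0.0721 without 1 library; list adjusted p = 0.731), and Cyp1a1 was not past the threshold (adjusted p = 0.577). Vcam1 (-1.96, SE 0.25, adjusted p = 0.00638) and Bcl3 fell among NF-kappaB targets (list adjusted p = 0.854), Plin4 and Pnpla2 among adipocyte genes (0.882), and Plin2 among sebaceous genes while Fasn rose (0.882). Monocyte and macrophage genes (Ccr2 rose, F13a1, Cd163 and Msr1 fell; 0.576), mast cell genes (Tpsb2 fell; 0.149), NRF2 targets (Sqstm1 fell; 0.0969), itch genes (Osmr fell; 0.437), immediate early genes (Ier3 fell; 0.614) and homeostatic differentiation genes (Rptn rose; 0.944) had the adjusted p given after each. Many of these single calls were lost without 1 library: in 5 of 6 fits for Fasn (adjusted p up to 0.104), in 4 for Bcl3 (0.112), F13a1 (0.126), Cd163 (0.133), Msr1 (0.141), Ier3 (0.13), Plin2 (0.14) and Tef (0.144), and in 3 for Ccr2 (0.0885) and Nfil3 (0.121). They were lost in 2 fits for Pnpla2 (0.0648), Tpsb2 (0.109), Sqstm1 (0.0727) and Osmr (0.101), and in 1 for Ckmt2 (0.059) and Rptn (0.0647). No member passed in the hyperproliferation (0.679), hair follicle (0.356), cholesterol (0.443), gamma-delta T cell (0.731), nerve (0.565) and mitochondrial (0.882) lists. The gamma-delta and mitochondrial medians, -0.02 and 0.04, differed in sign from their tests. Several of these lists passed in fits without 1 library. Without IMQ replicate 2 the hyperproliferation list passed downward (0.00266), the homeostatic list turned and passed upward (0.00185), and the hair follicle (0.0239) and NRF2 (0.0247) lists passed downward. Without IMQ replicate 1 the hair follicle (0.00868) and adipocyte (0.00513) lists passed, without bergapten replicate 1 the cholesterol list (0.00525), without bergapten replicate 2 the mast cell (0.0211) and NRF2 (0.0446) lists, and without IMQ replicate 3 the NRF2 list (0.0465).

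**Figure D3:**
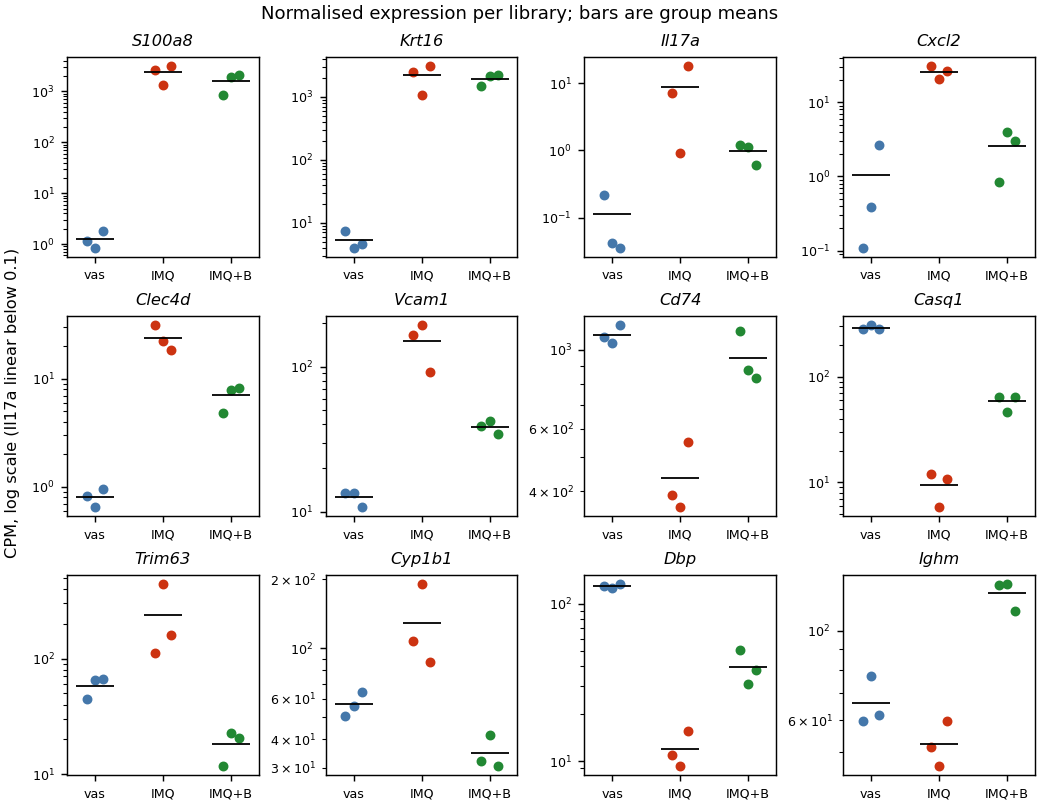
Normalised expression in CPM of 12 genes, 1 point per library, with group means as bars and a log axis (linear below 0.1 for Il17a). Cd74 lies at a mean of 435 CPM in IMQ skin and 944 CPM with bergapten, and Krt16 at 2196 and 1952 CPM.

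The third comparison, IMQ with bergapten against vaseline, shows how far the treated skin stood from unchallenged skin. Stress keratin and IL-36 genes were still far above vaseline: Krt16 was 363-fold, S100a8 1265-fold and Il1f6 151-fold higher. All 32 cell cycle genes were higher, with a median of 1.97, and 21 of 22 skeletal muscle genes were lower, with a median of -1.87. In the edgeR test 7270 genes passed (3763 higher, 3507 lower), of which 3151 differed at least 2-fold. The groups did not overlap for 59.2% of all genes, where chance gives 10%.

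The cell cycle list passed with adjusted p = 3.08e-11 (adjusted p = 0.429 with an estimated correlation), the hyperproliferation list, 26 of 28 higher, with adjusted p = 2.93e-21 (adjusted p = 0.234 with an estimated correlation), and the muscle list with adjusted p = 1.01e-13 (adjusted p = 0.105 with an estimated correlation). Interferon genes were lower than in vaseline in 10 of 28 cases, including Usp18 (-2.34, SE 0.26, adjusted p = 9.25e-05) and Ifi27l2a (-2.79, SE 0.67, adjusted p = 0.0128), and none was higher (list adjusted p = 0.000211; adjusted p = 0.586 with an estimated correlation). Of the dendritic and Langerhans cell genes 6 were higher and 3 lower of 22 (list adjusted p = 0.694), where Clec10a fell by 1.90 (SE 0.15, adjusted p = 1.52e-05) and Itgax rose by 0.66 (SE 0.11, adjusted p = 0.000854), and the median of 0.04 and mean of -0.034 differed in sign. The p53 median of 0.001 and mean of -0.083 also did (list adjusted p = 0.694). Il17a was 7.86-fold higher, which missed the threshold (SE 1.38 on the log2 scale, adjusted p = 0.121), while Il23a passed (4.57-fold, adjusted p = 0.0174), a call lost without bergapten replicate 2 (adjusted p = 0.0726).

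A further question crossed the first 2 comparisons. Among the 638 genes that passed in both, 520 moved 1 way with IMQ and the other way with bergapten: 261 rose and then were lower, such as Vcam1 and Clec4d, and 259 fell and then were higher, such as Cd74, Dbp and Casq1. The other 118 moved the same way in both, such as Usp18, Myh4 and Clec10a. Of the 520, 225 still differed from vaseline in the direction of the IMQ change and 272 were not past the threshold against vaseline. Most IMQ changes remained with bergapten: 5721 genes passed against vaseline in the same direction with and without it, and 23 in opposite directions. Over all genes those fold changes against vaseline, which share the vaseline libraries, correlated at r = 0.894. Because the IMQ libraries enter the first 2 comparisons with opposite signs, chance alone makes their fold changes run in opposite directions. The covariance of those log2 fold changes across genes was -0.203 (r = -0.362). The spread between the shared IMQ libraries alone gave -0.0793. In 20 simulations of unchanged groups, with the same spread in every group, the covariance was -0.0438 (r = -0.494). Independent lists of these lengths would share 189 opposite and 186.6 same-way genes. The count of 520 fell to 261, 274 and 261 without vaseline replicates 1, 2 and 3, rose to 986 without IMQ replicate 3, and fell to 85, 223 and 121 without bergapten replicates 1, 2 and 3.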

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

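Of these settings, only the fit without replicate 2 of IMQ and of IMQ with bergapten together was chosen after the results were seen. Counts of changed genes for IMQ against vaseline ran from 6218 to 8212 without 1 library, and for bergapten against vaseline from 5550 to 6306; a minimum fold of 2 left 3299 and 3151. For bergapten against IMQ the 869 genes became 489 with replicate number as a block (464 shared with the 869, in the same direction), 1802 with DESeq2 (868 shared), 130 in a fit of only the 6 libraries (127 shared), 355 with a minimum fold of 2, 552 without both replicates 2 (409 shared), and 139 to 1711 without 1 library. The labels do not say that replicate numbers pair samples. Deviations from the group means correlated at r = -0.091 to 0.176 between libraries of 2 groups with the same number and at -0.175 to 0.115 between others. For bergapten against IMQ the same-number values were -0.062, 0.067 and 0.176, and only bergapten replicate 3 correlated best with its own number. The 520 genes that moved in opposite directions became 287 with the block, 985 with DESeq2, 346 without both replicates 2, and 85 to 986 without 1 library. Lists past the threshold numbered 20, 11 and 20 in the 3 comparisons, and 22, 11 and 20 with the block. They numbered 19 to 23, 10 to 14 and 19 to 21 without 1 library, and 0, 0 and 0 with a correlation estimated per list. In the fry test for movement in 1 direction, 24, 1 and 21 of 31 lists passed. RLE size factors moved the median of all genes by at most -0.0118. Among genes taken by the naming rule, 5, 45 (of 144) and 6 in the 3 comparisons lost their call in at least 1 fit without a library, and for bergapten against IMQ 42 of 139 lost it in a fit of only the 6 libraries, 22 of 143 without both replicates 2, 18 of 144 with the block, 13 of 144 with no filter and 0 with DESeq2, where 31 of 142 gained one. Those totals include genes not past the threshold in the main fit, which had no call to lose. The shares of calls that were lost are therefore larger than these totals give. Some estimates turned sign. With RLE, the immediate early list did so for bergapten against vaseline (adjusted p = 0.977). Without both replicates 2, so did the interferon and immediate early lists for IMQ against vaseline (0.661 and 0.591) and, for bergapten against IMQ, the homeostatic (0.00321), sebaceous (0.488), cholesterol (0.488), adipocyte (0.242), skeletal muscle (0.774), gamma-delta (0.904), nerve (0.69) and immediate early (0.774) lists and the genes Cyp1a1 (log2 -0.30), Scart2 (-0.0844) and Trgc4 (-0.011). Adjusted p of lists that turned without 1 library ran, for bergapten against IMQ, from 0.00513 to 0.935 (adipocyte), 0.00868 to 0.545 (hair follicle), 0.318 to 0.889 (aryl hydrocarbon receptor), 0.00525 to 0.887 (cholesterol), 0.363 to 0.922 (circadian), 0.106 to 0.889 (gamma-delta), 0.00185 to 0.971 (homeostatic), 0.00266 to 0.901 (hyperproliferation), 0.179 to 0.79 (immediate early), 0.545 to 0.834 (mitochondrial), 0.131 to 0.674 (monocyte), 0.1 to 0.75 (nerve), 0.0875 to 0.928 (NF-kappaB), 0.268 to 0.641 (sebaceous) and 0.169 to 0.859 (muscle). For IMQ against vaseline they ran from 0.145 to 0.975 (immediate early) and 0.000114 to 0.679 (interferon), and for bergapten against vaseline from 0.205 to 0.913 (immediate early). These ranges cover all 6 fits without 1 library, whether the list turned in them or not. Of the fits in which a list turned, only that of the homeostatic list without IMQ replicate 2 passed (adjusted p = 0.00185). Genes that turned for bergapten against IMQ ran in log2 fold change from -0.50 to 0.15 (Krt16), -5.21 to 0.97 (Krt27), -7.20 to 0.66 (Krt71), -1.07 to 0.0696 (mt-Nd3), -0.0711 to 0.88 (Scart2) and -0.0933 to 1.03 (Trgc4). The 6 libraries of a comparison make only 10 splits, too few for a share under 0.05. All splits but the real one mix the 2 groups, so a real difference adds to their spread and lowers their gene counts. Low gene counts in those splits therefore cannot decide on chance. The real split and the highest other gave 7783 and 1 genes for IMQ against vaseline, 869 and 0 for bergapten against IMQ, 7270 and 0 for bergapten against vaseline, and 520 and 0 opposite genes, with 1 split (the real one) giving as many in each. For lists they gave 20 and 20, 11 and 19, and 20 and 19, with 2, 8 and 1 of the 10 splits giving as many.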

Other observations

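Pathways named in the deposited table added groups outside the fixed lists; the pathway tests and the lists named below, and the genes named in this part, were chosen after the results were seen. Among genes that fell with IMQ, 19 of 37 in pyruvate metabolism fell where 8.59 were expected (Fisher's exact test, adjusted p = 0.0328). So did 14 of 27 in the citrate cycle (6.27 expected), 21 of 47 in the breakdown of branched-chain amino acids (10.91 expected), 10 of 16 in fat digestion and absorption (3.72 expected) and 11 of 19 in chondroitin and dermatan sulfate synthesis (4.41 expected), each with adjusted p = 0.0466. No pathway passed among genes that rose with IMQ (lowest adjusted p = 0.123, Notch signaling, 9 of 12). Among genes higher with bergapten than with IMQ alone, the pathways past the threshold were cholinergic synapse (7 of 36, 0.92 expected, adjusted p = 0.00453), gastric acid secretion (6 of 32, adjusted p = 0.0115), insulin secretion (5 of 26, adjusted p = 0.0268) and circadian entrainment (5 of 30, adjusted p = 0.0402). None passed among genes that were lower (lowest adjusted p = 0.0822, calcium signaling, 9 of 61).

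All 6 tests of explanations below were chosen only after the results were seen. A first pattern is the movement of 520 of 638 genes in opposite directions with IMQ and then with bergapten. The shared IMQ libraries alone would give some of this, but with no IMQ library in both fold changes the covariance was still -0.1253, -0.1787 and -0.0676. A single divergent IMQ library as the whole cause also met a contrary value: with any 1 IMQ library left out and none of the others in both fold changes, the covariance was below 0 in all 6 pairs (highest -0.0264), although the count of 520 ran from 85 to 986 without 1 library. An effect of bergapten may underlie the pattern, as a hypothesis. The time since the last IMQ dose and the gel without bergapten were not tested and stay open.

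A second pattern is that muscle genes moved both ways with bergapten, Casq1 up and Myh4 down. The SD of the 22 members' log2 fold changes was 5.16 times their median standard error, which restates the pattern. Adjusted over the list alone, 3 members rose and 6 fell. More or less muscle in the sampled skin, as the whole cause, would move all members 1 way, so the pattern itself argues against that for these genes. A change in the amount of muscle as part of the pattern stays open. A fasting and glucocorticoid response, which IMQ-treated mice that eat less could show, was tested as another explanation with a list of 30 genes, of which 9 fell with bergapten, including Fkbp5 by 2.46 and Fbxo32 by 2.09, and 1 rose. The list's median was -1.01, with p = 1.25e-10 at the preset correlation, p = 0.0186 with fry and p = 0.127 with an estimated correlation, which keeps it open. With IMQ against vaseline 9 rose and 2 fell (median 0.39, p = 0.0486 at the preset correlation, p = 0.607 with an estimated correlation, p = 0.252 with fry). With bergapten against vaseline 0 rose and 9 fell (median -0.47, p = 0.0103 at the preset correlation, p = 0.507 with an estimated correlation, p = 0.131 with fry).

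A last pattern is the fall of collagens with IMQ: all 8 fell, by a median of -2.55, and Col1a1, Col1a2, Col3a1 and Sparc together took 9.92% to 10.493% of counts in vaseline and 0.709% to 1.97% in IMQ skin. Fewer fibroblasts, as the whole cause, would lower other fibroblast genes alike, but the median of 18 receptor and transcription factor genes lay 1.97 log2 units above the collagens. Those genes still had a median of -0.59 (12 fell, 0 rose, p = 0.0367 with an estimated correlation), so a smaller loss of fibroblasts stays open. Dilution of the dermis by a thicker epidermis, as the whole cause, would lower endothelial genes as much, but their median lay 2.89 log2 units above the collagens. Of the 18 endothelial genes 8 rose and 1 fell with IMQ. They may have changed by themselves, so this gap cannot decide on dilution. Skeletal muscle (median -1.63), nerve (-0.92), adipocyte (-0.95) and sebaceous (-1.16) genes were also lower, by less than the collagens, so dilution stays open. Less collagen mRNA per fibroblast was not tested and stays open as a hypothesis.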
